A study of Vitis vinifera with 2 samples.

How the data were processed

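RNA was sequenced from wounded grape (Vitis vinifera) tissue in 2 libraries. In 1 library the wound had received 10 µL of a suspension of the yeast Yarrowia lipolytica, and in the other the same volume of sterile water. Both were kept at 20 °C and taken 3 days after treatment. Groups follow the sample titles and the treatment protocol, because the strain label names the yeast for both samples, the water control included. The series text speaks of 2 types of tissue, and the sample labels give only wound tissue with and without the yeast. Each group has n = 1, so no test was made, no p-value is given, and no difference has a replicate check.

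The submitters' processing notes name HISAT2 without a version and HTSeq 0.6.1, without saying what each did. The genome build and the annotation are not named in the sources used here, though the sequences of the files carry versioned identifiers. Per the file headers, each library has a table of the same 53908 transcript models with a gene name, position, strand, exon number, length, mean per-base coverage (a signal not scaled to depth) and FPKM, which is fragments per kilobase of transcript scaled to the size of the library. Coverage divided by FPKM was 1 constant in each library, 5.90 in the control and 6.34 in the treated library. Names beginning with MSTRG mark transcript models that carry no annotated gene name in the files.

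A deposited table of the whole series gives 1 value per gene and library, 31144 rows in all, under the name FPKM. How the authors made these deposited values is not given in the sources used here, and they were treated as a score, because they are not FPKM of the genes they stand beside. Of 16526 loci tested, 16525 had a value equal to the aligned bases of the locus divided by a whole number of bases (tolerance 0.01). That whole number was the length of the locus's own transcript in 4 of 9184 loci with a single transcript. For 44.8% of those loci the length used was more than 2-fold off. Ratios between the libraries were mostly kept, since the divisor is the same in both: 93.8% of 13259 genes had a log2 ratio within 0.1 of the ratio from the transcripts. Levels of different genes in that table cannot be compared.

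Gene FPKM was therefore summed over the transcripts of each gene name, or of each locus where no name is given. The deposited gene table had been chosen first as the measurement, with this sum as a check on it. They were exchanged after the values were seen. A gene was measured when its FPKM was at least 1 in either library. The ratio was log2((treated FPKM + 1)/(control FPKM + 1)), and a gene was counted as higher or lower at 2-fold on this scale, which understates the difference of low genes. Folds printed beside FPKM values are plain ratios without the pseudocount.

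Depth came from coverage times transcript length: 5703223936 aligned bases in the control and 6162289390 in the treated library. Transcripts with very few aligned bases piled up at whole multiples of 150 and 300 bases, which was read as pairs of 150-base reads. The read length is not stated in the labels. One fragment equivalent was thus taken as 300 bases, giving 19010746 and 20540965. Intervals of a fold are exact binomial 95% intervals on rounded fragment equivalents, with their relative width carried to the FPKM ratio. They cover counting error only and say nothing of variation between berries or wounds. This form replaced an earlier one after the interval of MRIP1 was seen to exclude its own FPKM ratio. A gene with 1 kb of transcript and 3 fragments would have an FPKM of 0.152 in the control and 0.142 in the treated library.

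The gene lists, their themes and the rule for named genes were written before the data were examined. The rule takes the 15 highest and 15 lowest ratios among genes with a name and an FPKM of at least 10 in either library, up to 4 members of each list with an FPKM of at least 5, the most abundant member of each list, and at most 2 unnamed identifiers in each direction. The lists had been defined by words in product descriptions or by locus tags, and neither could be joined to the files. Membership was therefore assigned by hand from gene symbols and synonyms, after the values of all symbols had been printed. Of 37 lists, 26 had at least 1 symbol in the files and 13 had at least 3 measured members. The 11 others, for ERF and NAC factors, auxin response, NLR proteins, receptor-like kinases, wall loosening, ribosomal proteins, cuticle, seed, secondary wall and cell division, had no symbol, so markers of skin, seed and vascular tissue could not be checked. The result of 1 gene, and of the list that rests on it, is not reported here. A further 5 lists were added after the values were seen and stand apart. The rule for the highest and lowest genes was first applied to symbols alone and then extended to numbered genes that have a synonym in the reference table.

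Synonyms and chromosome numbers came from a RefSeq gene table of another Vitis vinifera assembly, ASM3070453v1, in which 89.1% of the 29498 gene names of the files were found. A chromosome number was given to a sequence of the files when its genes lay on 1 chromosome of that table, with shares from 99.3% to 99.9%. Coordinates are those of the files. For lists with at least 3 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is not a test. Apart from the organelle list, members were assigned after values had been printed, so a percentile is not independent evidence.

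Alternatives were pseudocounts of 0.1 and 5, no filter, an FPKM of at least 10, rescaling to a median ratio of 0 or by the upper quartile, the TPM scale, the deposited gene table, a 4-fold threshold, 5 expression bins, and transcripts of single-transcript genes. Added after the values were seen were a minimum of 10 fragment equivalents with an interval beyond 1, leaving out organelle sequences, and joining transcripts by locus. The counting of higher and lower genes was tested on simulated data for the treated over control comparison with 22746 genes. All 100 genes simulated 3-fold higher were recovered and 89 of the 100 simulated 3-fold lower. The pass mark for that step was lowered from 90 to 80 after this result, since the pseudocount takes low genes under 2-fold. With counting noise alone, 6 genes came out higher and 3 lower. Genes at 0 in the control were not simulated. The changed genes were drawn only from those above a minimum of fragments and FPKM in the control. Recovery among the lowest measured genes is therefore not known. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.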

Results

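The series asked which grape genes tied to resistance differ in expression when a wound is treated with Y. lipolytica, a yeast. The data are 1 RNA library from wound tissue given sterile water and 1 from wound tissue given the yeast, both taken 3 days after treatment. The control library held 19010746 fragment equivalents and the treated library 20540965. Of 30485 genes in the tables, 15478 had an FPKM of at least 1 in the control and 14826 in the treated library. All values below are FPKM of single libraries, given as control and then treated, and brackets hold 95% counting intervals.

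In the treated library, both stilbene synthases and all 3 phenylpropanoid entry enzymes measured in the lists were at least 2-fold higher than in the water control. So were 3 of 4 PR10 proteins measured in the lists. Apart from the organelle list, lists could draw only on genes with a symbol (329 of 16040 measured genes) or a synonym (36). Counts of list members are therefore not counts of whole families. Of 8330 genes with an FPKM of at least 10 in either library, 189 were named by a symbol or synonym. The largest ratio among these named genes was that of GST1, a glutathione S-transferase, at 14.8 and 175 FPKM, 11.8-fold higher (10.395 to 13.46). GER7, a germin-like protein, stood at 25.0 and 242 FPKM, 9.69-fold higher (8.783 to 10.703). Its span overlaps that of LOC104881406 (0 and 12.8 FPKM), so how fragments were split between the 2 is uncertain. The lowest ratio among these named genes was that of the aquaporin PIP2;3, a water channel of the plasma membrane. It stood at 34.6 and 6.99 FPKM, 0.202 times the control (0.171 to 0.238). Among 16040 measured genes, 1004 (6.26%) were at least 2-fold higher in the treated library and 587 (3.66%) at least 2-fold lower. At 4-fold the counts were 312 and 33.

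The median log2 ratio of all measured genes was -0.28, and 73.5% of genes lay below 0. Higher genes made up 63.1% of those past 2-fold, and 82.0% after rescaling to a median ratio of 0, where 1351 genes were higher and 296 lower. With a pseudocount of 0.1 lower genes were the majority, at 1540 against 1251 higher genes, or 44.8% higher. Ratios of gene groups are to be read against this median, which rescaling moved to -0.01. Markers of skin, seed and vascular tissue could not be checked, so how far the tissue make-up of the libraries differed is unknown.

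Stilbene synthases are the enzymes that make resveratrol, and both that carry a symbol were higher in the treated library. STS (chromosome 16, 16507942 to 16711818) stood at 379 and 2121 FPKM, 5.59-fold higher (5.47 to 5.72). VINST1 (chromosome 16, 16698300 to 16699842) stood at 101 and 564 FPKM, 5.57-fold higher (5.33 to 5.82). MYB14, a transcription factor known to activate grapevine stilbene synthase genes, stood at 37.1 and 136 FPKM, 3.68-fold higher (3.36 to 4.03). The genome build behind these coordinates is not named in the sources used here. STS is summed over 2 loci that span other genes, and stilbene synthases are near-identical copies, so how fragments were split among them is uncertain.

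STS and VINST1 lay in a stretch of chromosome 16, from 16286710 to 16711818, in which 29 consecutive measured genes, ordered by their start, were each at least 2-fold higher in the treated library. This stretch was picked out after its values were seen. Its genes together held 1703 FPKM in the control and 9435 FPKM in the treated library, 5.54-fold more, and 23 of them were at least 4-fold higher. Their share of all FPKM was 0.220% in the control and 1.25% in the treated library. Many of these gene models overlap, so their values are not independent of each other.

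**Figure D1:**
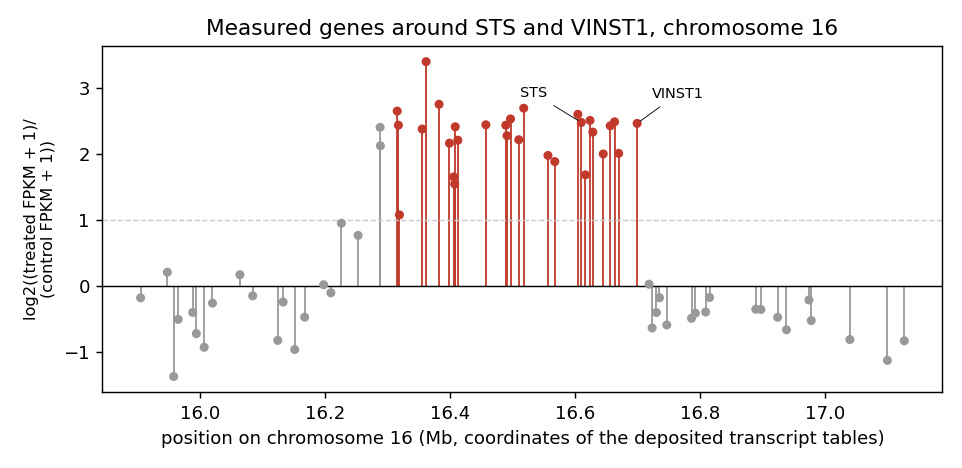
Log2((treated FPKM + 1)/(control FPKM + 1)) of measured genes (y axis) by midpoint on chromosome 16 in Mb (x axis), 1 library per group. Red points are the 29 consecutive genes, with ratios from 1.08 to 3.40, grey points are other genes around them, and the dashed line marks a ratio of 1.

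The listed enzymes at the entry of the phenylpropanoid pathway were all higher in the treated library, 3 of 3 measured members. Their median log2 ratio was 1.96, or 2.23 above the median of all genes. GVVPAL2, a phenylalanine ammonia-lyase (chromosome 16, 598465 to 616183), stood at 39.8 and 214 FPKM, 5.38-fold higher (5.12 to 5.66). LOC100245997, which has the synonym PAL, stood at 42.8 and 169 FPKM, 3.95-fold higher. 4CL, which activates coumarate, stood at 19.0 and 56.2 FPKM, 2.96-fold higher. The list median lay at percentile 99.62 of matched random lists. The ammonia-lyase genes are close copies, so their separate values are uncertain. In the lignin branch, the single measured member LOC100233087 (synonym CCOAMT) stood at 10.0 and 13.8 FPKM.

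None of 11 measured enzymes of the flavonoid and anthocyanin branch was past 2-fold, and their median log2 ratio was -0.44, or -0.16 relative to all genes, at percentile 5.82. Relative to all genes this difference was 0.00 with a pseudocount of 5. Chalcone synthase, which uses the same substrates as stilbene synthase, had 2 genes in the list: CHS3 stood at 27.3 and 15.8 FPKM, and CHS at 17.8 and 11.8 FPKM. CHS is summed over 4 transcripts and its value is uncertain, at 0.664 times the control by FPKM and 0.812 times in aligned bases. LDOX stood at 59.5 and 40.6 FPKM, while the chalcone isomerase CHI stood at 188 and 325 FPKM, 1.73-fold higher. FAOMT, named after its values were seen, stood at 0.698 and 2.04 FPKM. It was within 2-fold with the pseudocount of 1 but 2.92-fold higher without it (1.33 to 6.41).

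PR10 proteins, a family of small defence-related proteins, were higher in 3 of 4 measured members, with a median log2 ratio of 1.60 at percentile 99.86. This median was 0.80 with no filter on low values, 2.13 for members with an FPKM of at least 10 and 2.15 in the deposited gene table. PR10.3 (chromosome 5, 1251107 to 1252030) stood at 388 and 2359 FPKM, 6.07-fold higher (5.91 to 6.24). PR10.8 stood at 33.6 and 150.3 FPKM and PR10.2 at 680.05 and 1422 FPKM. PR10.4, the remaining member, had 0.253 and 1.18 FPKM. These genes are close copies, which leaves their split uncertain.

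Chitinases, which cleave chitin of fungal walls, were higher in 2 of 3 measured members, with a median log2 ratio of 1.34 at percentile 98.05. This median was 0.57 with no filter on low values and 0.58 in the deposited gene table. CHI4C stood at 226 and 697 FPKM, 3.08-fold higher (2.98 to 3.19), and LOC100232985, with the synonym chitinase, at 63.5 and 162 FPKM. CHI4D, the most abundant of them, stood at 6227 and 5468 FPKM, 0.878 times the control, with a log2 ratio of -0.19 that turned to 0.11 after rescaling to a median of 0. The 2 listed thaumatin-like proteins were within 2-fold, with TL1 at 501 and 665 FPKM and TL3 at 5988 and 5931 FPKM. The 2 listed beta-1,3-glucanases were low in both libraries. G1 stood at 1.69 and 0.946 FPKM and LOC100265368, named after its values were seen, at 0.339 and 1.55 FPKM. The polygalacturonase inhibitor LOC100232865 (synonym pgip), a protein that blocks fungal pectin-degrading enzymes, stood at 293 and 966 FPKM, 3.30-fold higher (3.21 to 3.40). The lists for terpene synthases, PR1 proteins and class III peroxidases held only 1, 2 and 1 genes, and none of these reached an FPKM of 1. This does not describe the rest of these families.

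Genes of hormone synthesis and signalling differed among themselves. Of 4 measured genes in the jasmonate list, LOXO was higher, at 64.0 and 233 FPKM, 3.64-fold (3.51 to 3.78), and LOXA lower, at 117 and 57.2 FPKM, 0.489 times (0.469 to 0.510). LOX stood at 2.79 and 5.39 FPKM and OPR3 at 28.3 and 35.6 FPKM. The symbols do not show which of these lipoxygenases serves jasmonate synthesis. The list median was 0.54, at percentile 96.90. LOXA was within 2-fold under each rescaling, with a log2 ratio of -0.72 after rescaling to a median of 0. The ethylene receptor ETR1 stood at 25.6 and 18.8 FPKM. EDS1, a regulator of salicylate signalling, stood at 4.25 and 5.52 FPKM.

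**Figure D2:**
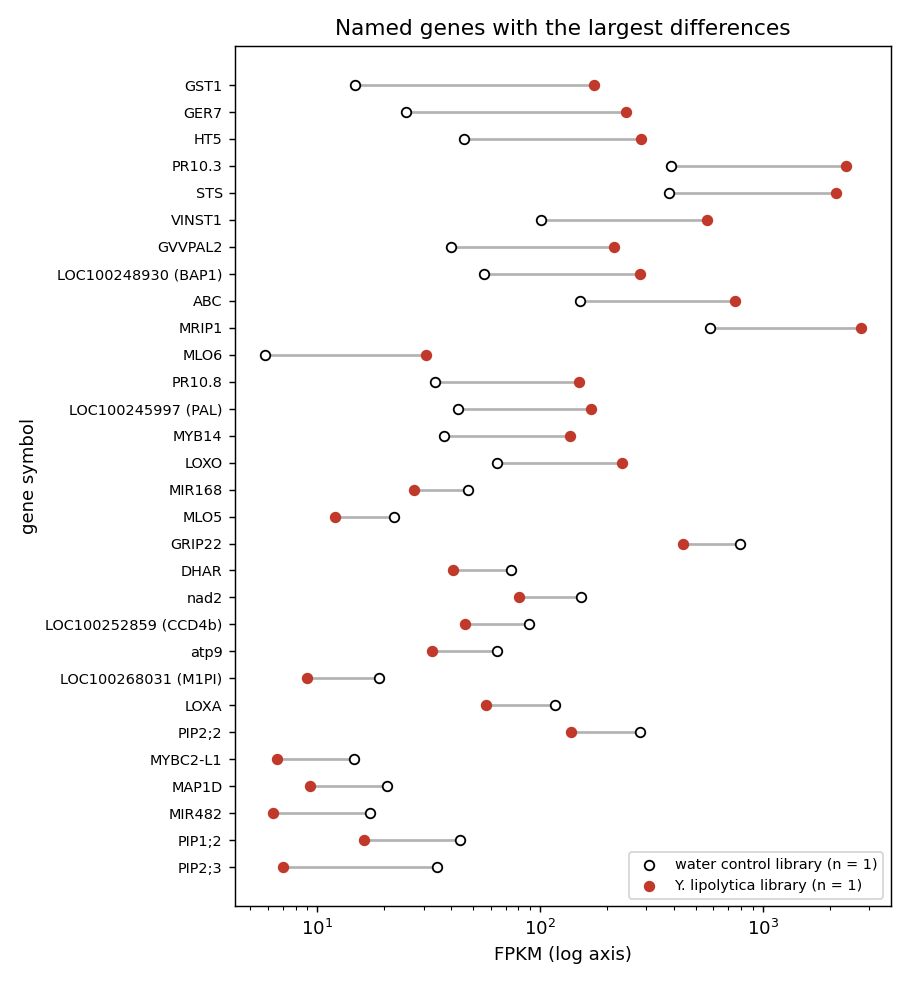
FPKM on a log axis (x axis) of the 30 named genes with the highest and lowest ratios (y axis), with 1 library per group. Open points are the water control library and red points the Y. lipolytica library, and ratios run from 11.8-fold higher for GST1 to 0.202 times the control for PIP2;3.

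Among other transcription factors, the gene written WKRY in the files stood at 20.7 and 60.4 FPKM. It alone was past 2-fold among the 3 listed WRKY genes, while WRKY20 stood at 5.46 and 3.69 FPKM. The WRKY median was -0.02, at percentile 83.06, and above 0 after each of the 3 rescalings. With an FPKM of at least 10 only WKRY was left, at 1.503. Of 8 measured MYB genes, MYB14 was higher and 2 were lower: MYBC2-L1 at 14.6 and 6.58 FPKM, and LOC100853472 (synonym MybA1) at 2.81 and 0.597 FPKM, the latter named after its values were seen. The MYB median of -0.26 lay at percentile 49.94. MYBC2-L1 was within 2-fold after rescaling to a median of 0, at -0.78.

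Sugar transport and cleavage genes went both ways, with 2 of 12 measured members higher and 1 lower and a median log2 ratio of -0.17 at percentile 70.33. HT5, a hexose transporter (chromosome 5, 4868712 to 4873422), stood at 45.5 and 284 FPKM, 6.25-fold higher (5.93 to 6.57). The cell wall invertase CWINV stood at 22.3 and 54.5 FPKM and the neutral invertase NIN1 at 45.6 and 85.5 FPKM. LOC100232961, with the synonym HT2, stood at 7.36 and 2.87 FPKM, and was within 2-fold after rescaling to a median of 0, at -0.88. The list's most abundant member, LOC100243643 (synonym SWEET15), stood at 989 and 751 FPKM. The sign of the sugar median turned with that rescaling, to 0.11.

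Listed glutathione S-transferases other than GST1 were within 2-fold, with GST4 at 35.7 and 27.5 FPKM and GST3 at 5.91 and 5.86 FPKM. The median of this list was -0.01, at percentile 80.11, was above 0 after each of the 3 rescalings, and was 1.56 for members with an FPKM of at least 10. No antioxidant enzyme of 4 measured was past 2-fold, with a median of -0.41 at percentile 20.67. APX, named after its values were seen, stood at 2.24 and 0.810 FPKM. It was within 2-fold with the pseudocount of 1 but 0.362 times the control without it (0.197 to 0.637). The superoxide dismutases MNSOD and SODCP stood at 754 and 569 FPKM and at 46.2 and 34.4 FPKM, and the catalase GCAT at 5.11 and 4.08 FPKM. Of 5 calcium sensors, CBL01 was higher, at 2.80 and 8.60 FPKM (within 2-fold with a pseudocount of 5, at 0.80), and CBL02 stood at 66.8 and 55.1 FPKM. The calcium median of -0.27, at percentile 53.22, turned to 0.02 after rescaling to a median of 0. The heat shock protein HSP101 stood at 38.2 and 51.8 FPKM.

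Several other named genes had large ratios. ABC, a transporter with the synonyms VvABCG44 and VvPDR14, stood at 152 and 747 FPKM, 4.93-fold higher (4.84 to 5.02). Its ratio in aligned bases was 4.43, outside this interval, and its span overlaps other genes, so its value is uncertain. LOC100248930, with the synonym BAP1, stood at 56.1 and 281 FPKM, 5.02-fold higher (4.66 to 5.40). MLO6, of a family of membrane proteins known for members that make plants susceptible to powdery mildew, stood at 5.83 and 30.9 FPKM, 5.30-fold higher (4.55 to 6.17). MRIP1 stood at 581 and 2750.3 FPKM, 4.73-fold higher, but its locus is shared with the very abundant GRIP4 (9967 and 8709 FPKM), its ratio in aligned bases was 17.0, and its log2 ratio in the deposited gene table was 0.39, so its value is uncertain.

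On the lower side, PIP1;2 stood at 43.5 and 16.2 FPKM, 0.373 times the control (0.330 to 0.422), and PIP2;2 at 281 and 138 FPKM. PIP2;2 was within 2-fold after rescaling to a median of 0, at -0.72. GRIP22, LOC100252859, DHAR, LOC100268031, MLO5 and MIR168 were among the 15 lowest named genes but lay within 2-fold. GRIP22, a ripening-induced gene, stood at 794 and 439.5 FPKM, and LOC100252859 (synonym CCD4b), a carotenoid cleavage dioxygenase, at 89.4 and 46.3 FPKM. DHAR, which regenerates ascorbate, stood at 74.1 and 40.5 FPKM. MAP1D stood at 20.6 and 9.32 FPKM and was within 2-fold after rescaling to a median of 0, at -0.79. LOC100268031 (synonym M1PI) stood at 18.9 and 8.99 FPKM, 0.475 times the control and so past 2-fold without the pseudocount. MLO5 stood at 22.0 and 12.04 FPKM. The microRNA precursors MIR482 and MIR168 stood at 17.3 and 6.35 FPKM and at 47.7 and 27.0 FPKM. They are short, at 117 and 132 bases, and MIR482 had 39.5 and 15.4 fragment equivalents. In the deposited gene table the values of MIR482 were 1.01 and 0.366. Its log2 ratio there was -0.56, which the pseudocount of 1 shrinks at such low values.

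The reference gene UBC2, a ubiquitin-conjugating enzyme, stood at 222 and 219 FPKM, 0.984 times the control (0.943 to 1.03), and its log2 ratio of -0.02 was 0.28 after rescaling to a median of 0. Fermentation enzymes were within 2-fold in 4 of 4 members, with a median of 0.04 at percentile 78.98. ADH2, an abundant alcohol dehydrogenase, stood at 4537 and 5315 FPKM, and ADH7 at 801 and 549 FPKM. The photosystem gene PSBP1 was near the measuring limit in both libraries, at 1.07 and 0.988 FPKM. Organelle-encoded genes took 0.137% and 0.108% of aligned bases. Of 86 measured organelle genes, ndhB and trnR-UCU were higher and psbI lower, each under 2 FPKM in both libraries. Of these trnR-UCU had 0.317 and 2.54 fragment equivalents and psbI 3.63 and 0.403, so neither difference was detectable at this depth. The organelle median was -0.22 at percentile 93.77, or 0.08 after rescaling to a median of 0. The mitochondrial genes atp9 and nad2, both within 2-fold, stood at 63.8 and 32.8 FPKM and at 153 and 80.9 FPKM, and the ribosomal 18Srrn at 161 and 125 FPKM. The value of nad2 is summed over 3 loci and is uncertain, with a log2 ratio of -0.91 that was -0.19 in the deposited gene table.

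**Figure D3:**
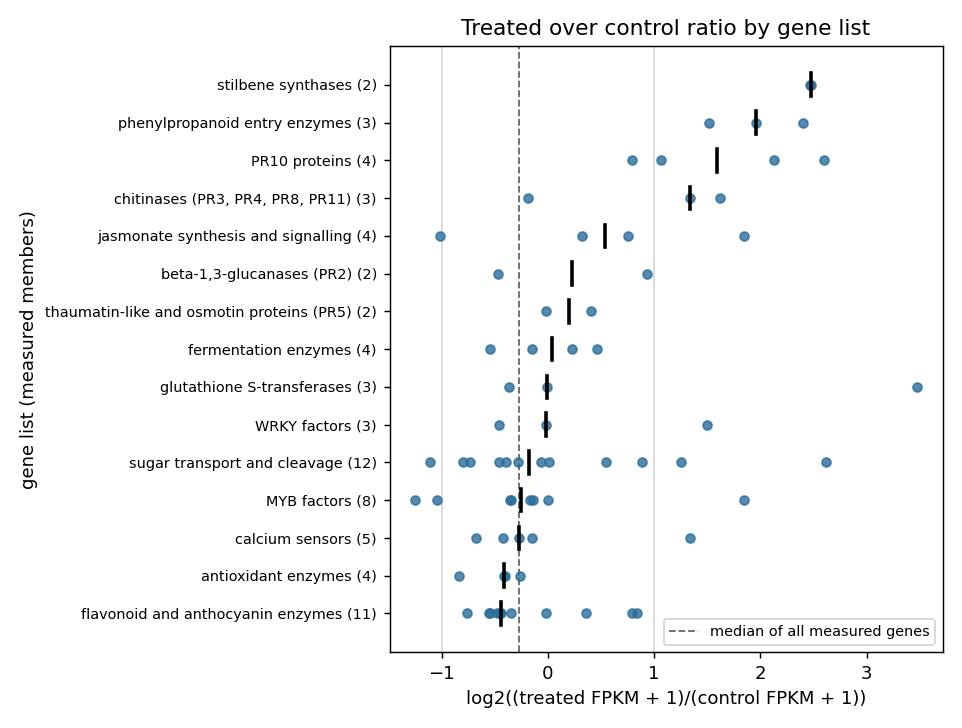
Log2((treated FPKM + 1)/(control FPKM + 1)) of each measured member (points, x axis) by gene list (y axis, number of members in brackets), 1 library per group. Black bars are list medians, from 2.47 for stilbene synthases to -0.44 for flavonoid and anthocyanin enzymes among the lists shown. The themes of these lists were fixed beforehand, and their members were assigned after values had been printed. The dashed line is the median of all genes at -0.28.

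At the level of transcripts, 23481 were measured, of which 1897 were at least 2-fold higher in the treated library and 1694 at least 2-fold lower. Of 4682 genes with more than 1 measured transcript, 298 (6.36%) had transcripts past 2-fold in both directions. In 273 of these the gene as a whole was within 2-fold. Among 8870 transcripts of genes with a single transcript, 677 were higher and 380 lower. These counts rest on how fragments were divided among the transcripts of 1 gene, which is not described in the sources used here.

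A few unnamed loci were listed at or near 0 in 1 library and well above it in the other. MSTRG.7818 was listed at 0 in the control and at 150.2 FPKM in the treated library, and MSTRG.17301 at 0 and 97.4 FPKM. LOC100267392 stood at 70.0 FPKM in the control and 0.0001 in the treated library, and MSTRG.11848 at 64.8 FPKM in the control and at 0 in the treated library.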

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

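No paired analysis was possible because each group has 1 library and no test was made, and there was no replicate to leave out. With 1 library per group the depth sets counting error only. Among the 80 genes chosen by the rule, none past 2-fold changed sign under any of 8 settings that gave it a value. Genes under a setting's filter have no value. This outcome was largely fixed in advance, since pseudocounts and filters cannot turn a sign and the rescalings were too small to. Only the deposited gene table could have turned one, and it rests on the same aligned bases. Of 36 genes chosen by the rule and past 2-fold, 28 stayed so under each setting that gave a value. CBL01, LOC100232961, LOXA, MAP1D, MIR482, MRIP1, MYBC2-L1 and PIP2;2 did not under at least 1. Genes named outside the rule were not in this count. Of 627 values of genes chosen by the rule, 473 lay within the counting interval of the gene's plain fold and 154 outside it. The values carry a pseudocount and the intervals do not. A value could therefore lie outside its interval without having changed between settings.

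Against 1004 higher and 587 lower genes, 312 and 33 passed 4-fold and 622 and 116 passed 2-fold with a pseudocount of 5, both fewer by construction. A pseudocount of 0.1 gave 1540 lower genes, an FPKM of at least 10 gave 232, and rescaling to a median of 0 gave 296. Higher genes made up 44.8%, 74.9% and 82.0% of genes past 2-fold under these 3 and 84.3% with a pseudocount of 5. No filter, the upper quartile and the TPM scale gave 1004, 1074 and 1088 higher and 587, 486 and 685 lower genes. The deposited gene table gave 1006 and 719, of which 847 and 398 were also past 2-fold by summed FPKM. Of the alternatives chosen after seeing the data, 10 fragment equivalents with an interval beyond 1 gave 988 and 571, leaving out organelle sequences 1002 and 586, and joining by locus 985 and 599. Transcripts of single-transcript genes gave 677 and 380 against 1897 and 1694 transcripts, fewer by construction.

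Of 208 list counts, 181 stayed the same or within 1.5 times. A pseudocount of 0.1 gave 1 higher flavonoid gene in place of 0, 1 lower antioxidant gene and 1 lower calcium sensor in place of 0, and 5 higher and 4 lower organelle genes in place of 2 and 1. With a pseudocount of 5, the lower MYB genes went from 2 to 0, the lower jasmonate gene, the higher calcium sensor and the lower sugar gene were lost (0 each), and organelle genes came to 0 higher and 0 lower. An FPKM of at least 10 left 1 lower MYB gene, 0 higher calcium sensors, 0 lower sugar genes, and 0 higher and 0 lower organelle genes. Rescaling to a median of 0 gave 2 higher flavonoid genes, 2 higher and 0 lower jasmonate genes, 1 lower MYB gene and 0 lower sugar genes. Upper-quartile rescaling gave 1 lower MYB gene and 0 lower jasmonate genes, the TPM scale 0 lower jasmonate and 2 lower organelle genes, and the deposited gene table gave 1 lower MYB gene and 0 lower organelle genes. With 5 expression bins the percentiles were 99.72 for phenylpropanoid entry enzymes, 99.91 for PR10 proteins, 98.64 for chitinases and 5.19 for the flavonoid list. Apart from the counts named as fewer by construction, the cause was not tested.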

Other observations

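The lists for aquaporins, CBL-interacting protein kinases, MLO proteins, germin-like proteins and S-adenosylmethionine synthetases were formed after the values had been seen, and the test of the lengths in the deposited gene table was also chosen after its result was seen. The resampling of genes for the median ratio was added after the medians were seen.

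Of 9 measured aquaporins 4 were at least 2-fold lower, PIP2;3, PIP1;2, PIP2;2 and the low TIP1;1 (1.27 and 0.0942 FPKM), and the median log2 ratio was -0.77, or -0.49 relative to all genes, at percentile 0.02 of matched random lists, a place that is not independent evidence, since the list was formed after low values had been seen. PIP1;3, the most abundant of them in the control, stood at 692 FPKM in the control and 478 in the treated library, and PIP2;1 at 88.4 and 51.4. TIP2;1, a channel of the vacuole membrane, went the other way, at 233 and 497 FPKM, 2.14-fold higher (2.06 to 2.22). The aquaporin median stayed below that of all genes under the 8 alternative settings, and PIP2;2 was within 2-fold under each rescaling.

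Of 17 measured CBL-interacting protein kinases, which act in calcium signalling, 3 were higher and 0 lower. CIPK02 stood at 87.2 and 214 FPKM, CIPK11 at 3.18 and 9.09, and CIPK19 at 5.07 and 12.5, and with a pseudocount of 5 the count was 1. Their median of 0.02 lay at percentile 97.74 and was -0.04 in the deposited gene table. The 4 measured S-adenosylmethionine synthetases were all below a ratio of 0 and within 2-fold (1 was past it with a pseudocount of 0.1), with METK2 at 827 and 699.99 FPKM and METK4 at 265 and 181, and a median of -0.47 at percentile 6.20. Of 5 MLO genes MLO6 alone was past 2-fold, and their median of -0.10, at percentile 78.61, turned to 0.18 after rescaling to a median of 0. Of the germin-like genes only GER7 and GER6 were measured, GER6 at 1.07 and 0.579 FPKM.

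Neighbouring genes were higher together. Among 14470 neighbouring pairs, 229 had both genes at least 2-fold higher, where 95% of 1000 shuffles of the ratios gave 43 to 70. Without pairs that overlap or share a locus 130 remained, against 41 to 67 in shuffles. This argues against overlap of the genes of a pair with each other as the whole cause. Pairs lying inside the span of another gene model were kept, such as LOC100246283 and LOC104877274 inside that of STS. The count therefore cannot decide whether overlapping gene models in general were the cause. There were 20 runs of at least 4 such genes, holding 143 genes, among them the stretch with STS and VINST1 and a run of 12 with GVVPAL2. The files give no product for the genes in these runs. A response to the yeast, a difference between the wounds and fragments shared among near-identical copies that do not overlap were not tested. These and overlapping gene models stay open.

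Most genes lay slightly below a ratio of 0, and without the pseudocount the median was -0.30 over the 14264 genes with an FPKM of at least 1 in both libraries. The 100 genes with the largest gain in FPKM took 5.96% of the control and 13.2% of the treated library, and with them left out and the rest rescaled the median was -0.1655 (-0.173 to -0.156 when genes were resampled). That it moved towards 0 follows from how the genes were chosen, and its size depends on their number. It was -0.24 with 10 genes left out, -0.07 with 500 and -0.04 with 1000, numbers added later. How much of the shift the share of such genes could account for therefore stays open. From the least to the most abundant of 5 equal parts of the genes, the medians were -0.39, -0.42, -0.34, -0.24 and -0.1919 (-0.207 to -0.177 when genes were resampled, 2853 genes). Resampling genes within these 2 libraries does not cover variation between libraries or wounds. For these libraries the medians argue against low counts or a difference in depth as the whole cause. They leave a contribution from low counts or depth open. Also open is a difference in RNA composition tied to the yeast or to the wounds sampled, which was not tested.

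Of 9 genes above 10 FPKM in 1 library and under 0.1 in the other, 77.7778% overlapped another gene or shared its locus, against 11% of 1000 other genes. Fragments given to different overlapping models in each library are therefore a candidate explanation for these genes, MSTRG.7818, LOC100267392 and MSTRG.11848 among them. The 2 without an overlap were MSTRG.17301, at 0 and 97.4 FPKM, and LOC100255087, at 0 and 10.97 FPKM, for which this explanation has no support here. MSTRG.17301 is a model with 1 exon and no strand, from base 1 to 561 of a sequence without a chromosome number. It had 0 and 1154 fragment equivalents, and where these came from was not tested. That MSTRG.7818 has an overlapping neighbour had been noticed before the share was computed, and a response to the yeast was not tested for these genes.

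In the deposited gene table, the length behind a value equalled that of the locus at the same rank in another alphabetical order for 12530 of 12530 loci whose partner has 1 transcript, against 0.0798% when the lengths were shuffled, after 6 orders had been tried in pairs. The matching orders differ in whether capital letters sort apart from small ones.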
